A study of Mus musculus with 12 samples.

How the data were processed

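SOX2, a transcription factor that maintains pluripotency, was mapped by chromatin immunoprecipitation followed by sequencing (ChIP-seq) in E14 cells, a mouse embryonic stem cell line. Per the labels, 12 libraries fell into 4 groups of 3 biological replicates: SOX2 ChIP and input DNA from asynchronous cells, and SOX2 ChIP and input DNA from mitotic cells. Per the labels' protocols, cells grew in medium with 10% serum, leukemia inhibitory factor, the GSK3 inhibitor CHIR99021 at 3 μM and the MEK inhibitor PD184352 at 0.8 μM. Mitotic cells were arrested overnight with nocodazole, a microtubule poison, then fixed, stained and sorted for H3S10p, a histone phosphorylation of condensed chromosomes. Chromatin was fixed with formaldehyde and sonicated before the pull-down.

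Per the submitters' processing notes, Bowtie2 version 2.2.1, MACS2 and the genome build mm10 were used; no version of MACS2 is given in the sources used here. Per the deposited names, peaks of ChIP against input were called once per condition on the 3 pooled replicates, and blacklisted regions were taken out. The deposited names also carry a q-value tag for each condition, read here as 0.01 for the asynchronous and 0.05 for the mitotic list, so the mitotic list had the looser threshold. Each of the 2 lists used here holds a chromosome, a start, an end and a name per peak; the deposited values are positions in bp (unit: other), with no score, fold, p, q or read count column. Replicates therefore have no values of their own, and no statement here rests on the spread between replicates. The sequencing depth is unknown. Intervals and limits for counts of 0 cover counting error only.

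Starts were converted to positions counted from 1. In the asynchronous list, 181 of 10532 entries repeated the coordinates of another entry with a different summit letter and were merged, which left 10351 distinct regions. The mitotic list had 84 distinct regions. Genes came from the RefSeq annotation of GRCm38.p6, the assembly that mm10 is a name for, as gene spans on 21 chromosomes. All 228 distinct genes of the fixed lists were matched among 21887 protein-coding genes. The annotation used here gave neither strand nor exons, and genome sequence was not used here.

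The tests, the samples they use, the alternatives, the gene lists and the rule for named genes were fixed before the data were examined. Several planned steps could not be carried out as written. Gene spans replaced transcription start sites. Location classes became gene end (midpoint within 1 kb of either end), inside a gene, up to 50 kb outside and further than 50 kb. They were assigned in that order, so a midpoint inside a gene but within 1 kb of an end counted as gene end. These classes stood in place of promoter, exon, intron and intergenic. Region width replaced a peak score for ranking and for the stronger part of a list. Width is not a measure of binding strength and also grows with depth. The planned test of SOX motifs was void without sequence. Interval overlaps were computed with numpy in place of bedtools.

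Mitotic and asynchronous regions were counted as shared with an overlap of at least 1 bp. The count was compared with 1000 random placements of the mitotic regions with the same widths on the same chromosomes (one-sided permutation p). Placements spanned each chromosome from its outermost gene or region on one side to that on the other; assembly gaps and mappability were not modelled. The width percentiles of shared and other asynchronous regions were compared by a two-sided permutation test with 100000 draws. Location classes were compared between mitotic regions and asynchronous regions without a mitotic overlap by two-sided Fisher's exact tests, Benjamini-Hochberg adjusted over 4 classes. For each of 11 gene lists, genes with a region midpoint within 50 kb of the gene span were counted against all other protein-coding genes by a two-sided Fisher's exact test, adjusted over the 11 lists. Random lists (10000 per list) matched on 10 classes of gene length and 5 classes of the gap to neighbouring genes gave a further comparison. Chromosome counts were compared by a chi-square statistic with 100000 permutation draws. Intervals are exact (Clopper-Pearson) at 95%; for a count of 0, the limit of 3 counts divided by the total is also given. The threshold for an adjusted p was 0.05.

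Named genes were chosen by rule. They were every listed gene with a mitotic region within 50 kb; the nearest protein-coding genes of the 15 widest regions of each list and of the shared regions; and up to 6 members per list with the most asynchronous regions within 50 kb. Some genes that the rule selects are not reported here. Nanog, Klf4, Tfcp2l1, Sall1, Kit, Myc, the listed pluripotency genes without a region and the genes named in the closing section outside this rule were singled out after their values were seen. So were the distances of mitotic regions to the nearest asynchronous region and the regions further than 50 kb from Sox2. Distances run from the region's midpoint to the gene span, and from edge to edge between regions.

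Alternatives covered the overlap rule, the type of random placement, regions wider than their list's median, merging within 500 bp, a gene-end class of 2.5 kb, windows of 10 kb, the nearest gene of each region, matched lists and leaving out X and Y. The overlap and gene list tests were tested on simulated data. With no planted overlap 2% of 100 runs were called, and with 25 planted overlaps 100% were. A simulated list of random genes was called in 1% of runs, and in 97% when 15 of its genes were given an added region. The planted overlaps outnumbered those found below. The simulated list was larger than every fixed list but pluripotency, and was called on an unadjusted p. These rates therefore do not give the power of the tests reported below. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Reads, input libraries by themselves and values per replicate were not analysed here.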

Results

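SOX2 binding was profiled in asynchronously growing mouse embryonic stem cells and in cells arrested and sorted in mitosis, with 3 ChIP and 3 input libraries per condition. The comparison addresses where the factor occupies the genome during mitosis relative to the growing population. Each condition is represented by 1 list of regions called on its pooled replicates, so counts and widths have no replicate error. All coordinates are on mm10.

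Asynchronous cells had 10351 SOX2 regions and mitotic cells had 84, a 123-fold difference and 0.812% of the asynchronous number. The mitotic regions were found at the looser of the 2 thresholds. The numbers in the peak names run to 15590 and 131, of which 5239 and 47 are not in the lists, so that these counts, and genes without a region, refer to the peaks listed. Asynchronous regions had a median width of 289 bp (interquartile range 226 to 381 bp) and together covered 3314 kb. Mitotic regions had a median width of 125 bp (107 to 156 bp) and covered 11.3 kb. At the smallest width of their list were 18 mitotic regions (21.4%), all 105 bp wide, and 460 asynchronous regions (4.44%), all 183 bp wide. The smallest widths differ between the lists, and depth is unknown, so widths were compared only within a list.

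The widest asynchronous region lay on Sox2 itself, at chromosome 3, 34650367 to 34652427. It was 2061 bp wide and covered 83.5% of the span of Sox2 (34649995 to 34652461). It held 5 listed summits, the most of any region, although some summits are missing from the list. The next widest, 1186 bp, lay inside Cdx2, which specifies trophectoderm, at chromosome 5, 147304062 to 147305247. Regions inside Vangl1, a planar cell polarity gene, and Pigl, an enzyme of GPI anchor synthesis, were both 1137 bp wide. They were followed by regions inside Svil, an actin-binding protein (1125 bp), Crtac1 (1017 bp), Garem1, an adaptor of growth factor signalling (1015 bp), and Atp8a1, a phospholipid flippase (965 bp). The other wide regions lay outside the nearest gene. These included regions 99.6 kb from the carbonic anhydrase gene Car2 and 36.9 kb from the glucose transporter gene Slc2a1. Others were 93.6 kb from the transcriptional repressor gene Zbtb20, 78.1 kb from Hsd17b3, 118 kb from Gm11677 and 236 kb from Plekhb2.

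The widest mitotic region, 217 bp, lay inside Spg11 at chromosome 2, 122097856 to 122098072, and the next, 216 bp, inside Mylk, the myosin light chain kinase, at chromosome 16, 34895818 to 34896033. Regions of 203 to 167 bp lay inside Rab3ip, Spag1, Mybl2, a transcription factor of the cell cycle, Pisd, Rmc1, Fras1, Rexo1 and Scube1. Others lay 29.5 kb from Grhl2, an epithelial transcription factor, 179 kb from Arid1b, a subunit of the BAF remodelling complex, 27.7 kb from Zfp640, 9.44 kb from Nyap1 and 125 kb from 4933412E24Rik. The regions at Rmc1 and Nyap1 had an annotated pseudogene within 10 kb.

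Of the 84 mitotic regions, 9 overlapped an asynchronous region, near Pisd, 4933412E24Rik, Nrarp, Pde9a, Izumo2, Gdi2, Abcg1, Zfp990 and Cd244a. The other 75 did not, and 10342 asynchronous regions had no mitotic counterpart. The shared region at Nrarp, a feedback regulator of Notch signalling, was at chromosome 2, 25180627 to 25180782, with its midpoint 0.054 kb outside the gene. At Abcg1, a cholesterol exporter, it was at chromosome 17, 31057331 to 31057446, 0.306 kb outside the gene. Inside genes were the shared regions of Pisd, which makes phosphatidylethanolamine (chromosome 5, 32739239 to 32739415), Pde9a, a cGMP phosphodiesterase (chromosome 17, 31463492 to 31463612), and Cd244a, a receptor of natural killer cells (chromosome 1, 171578563 to 171578672). Those near Izumo2 (chromosome 7, 44723458 to 44723576) and Zfp990 (chromosome 4, 145546632 to 145546745) lay 3.67 kb and 8.44 kb outside the gene. The shared regions near 4933412E24Rik (chromosome 15, 60141799 to 60141971) and Gdi2, a regulator of Rab GTPases (chromosome 13, 3341698 to 3341814), lay 125 kb and 196 kb from the gene.

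The shared fraction was 10.7% (exact 95% interval 5.02 to 19.4%). Random placement of the 84 regions gave a mean of 0.163 ± 0.406 (SD, 1000 placements) overlaps and at most 3, with a one-sided permutation p of 0.000999, the smallest that 1000 placements can give. Among the 42 mitotic regions wider than their median, 3 overlapped an asynchronous region, against 0.0870 in random placements (permutation p = 0.000999).

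**Figure D1:**
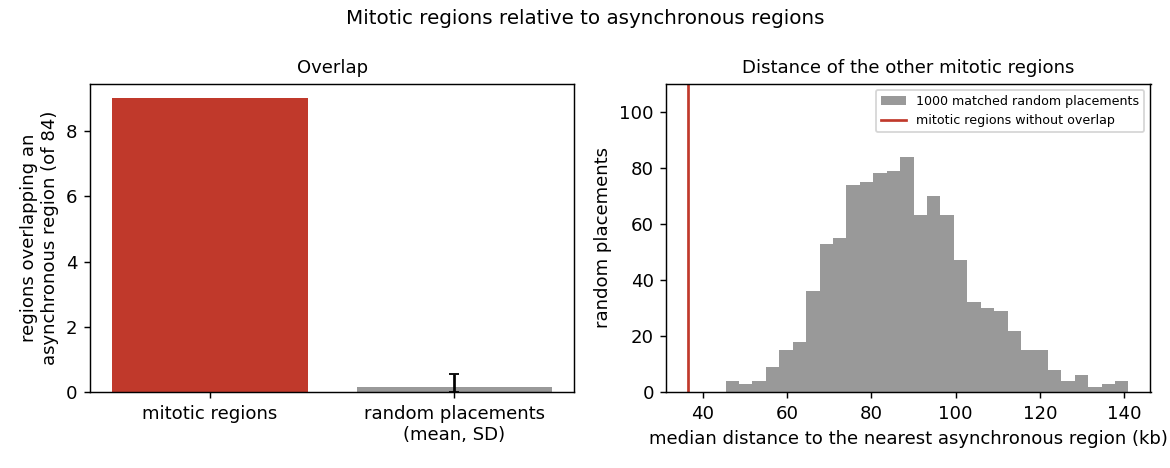
Left, number of the 84 mitotic regions that overlapped an asynchronous region (red bar, 9) beside the mean and SD of 1000 random placements on the same chromosomes (grey bar, 0.163 ± 0.406, the lower bar stopped at 0). Right, the median distance in kb of the 75 other mitotic regions to the nearest asynchronous region (red line, 36.6 kb) with the distribution of that median over 1000 placements matched on distance to genes (grey bars, number of placements), all of which lie to the right of the line.

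Mitotic regions without an overlap lay nearer to asynchronous ones than matched random placements did. One, whose nearest gene was Sall1, a zinc finger transcription factor, lay 3.52 kb from an asynchronous region at chromosome 8, 89012135 to 89012249. Another, 4.10 kb from an asynchronous region, had Myc as its nearest gene, 61.8 kb away, at chromosome 15, 61923489 to 61923593. A region inside Kit, a receptor tyrosine kinase, at chromosome 5, 75598522 to 75598626, lay 5.80 kb from an asynchronous region. The regions near Myc and Kit had the smallest width of the mitotic list, 105 bp, and that near Sall1 was 115 bp wide. Other regions without an overlap lay nearer than these, down to 1.74 kb. The median distance of the 75 regions was 36.6 kb, against 87.9 kb (central 95%, 59.6 to 123 kb) for placements matched on distance to genes (one-sided permutation p = 0.000999, the smallest possible). Within 20 kb of an asynchronous region were 26 of them, against 12.6 ± 3.21 (SD) in matched placements (permutation p = 0.002). Within 5 kb were 9 of the 75, against 3.66 ± 1.84 (SD) in matched placements (permutation p = 0.00899).

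The asynchronous regions that were shared with mitotic cells included wide and narrow ones. The region at Abcg1 was 737 bp wide, at width percentile 99.1 of the asynchronous list, and that at Nrarp 577 bp, at percentile 96.0. The regions at Pde9a and Izumo2, 185 and 214 bp wide, were at percentiles 5.33 and 19.3. Those near Gdi2, Pisd, Cd244a, 4933412E24Rik and Zfp990 were at percentiles 89.8, 86.9, 86.9, 60.04 and 34.7. The mean percentile was 64.2 ± 35.9 (SD, 9 shared regions) against 49.99 for the other 10342, a difference of 14.3 that did not pass a two-sided permutation test (p = 0.142). Wider regions are hit more often by chance: draws weighted by width, an alternative added after the data were seen, gave a mean difference of 7.16 (permutation p = 0.475).

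Mitotic regions lay inside genes, away from gene ends, more often than asynchronous ones. Of the mitotic regions, 51 (60.7%, exact 95% interval 49.5 to 71.2%) had their midpoint inside a gene and more than 1 kb from any gene end. Among them were those in Spg11, Mylk, Mybl2 and Kit. Of the asynchronous regions without a mitotic overlap, 4577 of 10342 (44.3%, 43.3 to 45.2%) were in this class. Random placement gave 38.8% and 38.9%. The difference passed Fisher's exact test (odds ratio 1.95, adjusted p = 0.0112). Gene ends held 4 mitotic regions (4.76%) and 7.46% of the asynchronous ones (Fisher's exact test, adjusted p = 0.527), where random placement gave 3.12% and 3.14%. Further than 50 kb from any gene were 13.1% and 21.1% (Fisher's exact test, adjusted p = 0.160), both below the 35.3% and 35.1% of random placement, and up to 50 kb outside a gene were 21.4% and 27.1% (adjusted p = 0.358). Exons, introns and promoters were not separated.

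Asynchronous SOX2 regions were concentrated around genes of the pluripotency network. Of 36 listed pluripotency genes, 32 (88.9%, exact 95% interval 73.9 to 96.9%) had a region within 50 kb, against 45.4% of the other protein-coding genes. The number of regions per gene had a median of 2 and reached 7, and summed to 85 when a region near several of the genes was counted for each. Jarid2, a Polycomb cofactor, had 7, and Esrrb, an orphan nuclear receptor, and Pou5f1, the partner of SOX2 on composite sites, had 6 each. Dppa5a, Fgf4, which signals exit from naive pluripotency, and Mycn had 4 each.

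At Pou5f1 (chromosome 17, 35506032 to 35510777), regions lay at 35502603 to 35503043 and 35503729 to 35504407, and a further one, at 35510230 to 35510842, reached across the gene's other end. Nanog, a homeobox factor of the same network, had 3 regions, at chromosome 6, 122702560 to 122703144, 122707154 to 122707624 and 122744873 to 122745072. The middle one spanned an end of the gene (122707489 to 122714633). Esrrb held 5 of its 6 regions inside the gene, the widest at chromosome 12, 86501535 to 86502157. Tfcp2l1, a transcription factor of naive cells, had 4. Klf4 had 1, at chromosome 4, 55477308 to 55477723, 49.6 kb from the gene. Sox2 had 3 regions within 50 kb and 5 further ones 92.9 to 135 kb beyond the end of its span. The listed genes without a region within 50 kb were Dppa2, Dppa4, Tdgf1 and Stat3, whose nearest regions were 103, 128, 194 and 270 kb away. No mitotic region lay within 50 kb of any of the 36 genes.

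**Figure D2:**
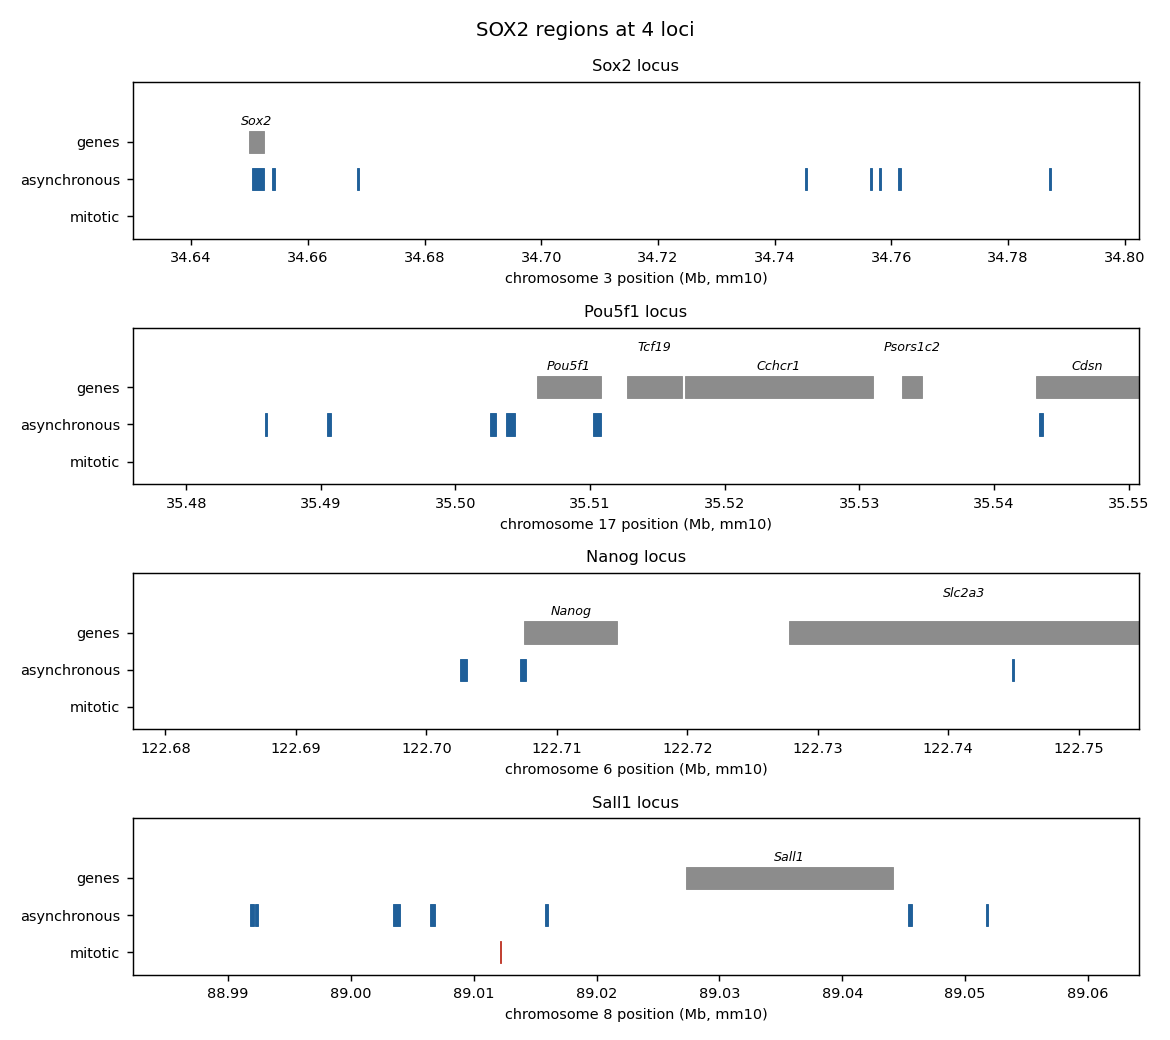
Maps of the Sox2, Pou5f1, Nanog and Sall1 loci (x axis, chromosome position in Mb on mm10), with protein-coding gene spans in grey, asynchronous regions in blue and mitotic regions in red, drawn to scale with a thin outline. Asynchronous regions lie on both sides of Pou5f1, Nanog and Sall1, and on Sox2 and to one side of it, the only mitotic region shown is the one 15.1 kb from Sall1, and the leftmost Sall1 block is a pair of neighbouring regions.

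Signalling genes were also often near a region. Of 24 genes of LIF, FGF, Nodal and Wnt signalling, 19 (79.2%, 57.8 to 92.9%) had one within 50 kb. Tcf7l1, a repressor in the Wnt pathway, had 5, and Jak2, a kinase downstream of LIF, Smad7 and Socs3, inhibitors of TGF-beta and JAK signalling, had 4 each. Fgfr1 and Lefty1, a Nodal antagonist, had 3 each. Of 16 formative and primed genes, 12 (75%, 47.6 to 92.7%) had a region. Etv5 and Lef1 had 4 each, and Epha2, Etv4, Foxd3 and Zic5 had 3 each. Zic5 and its neighbour Zic2 shared their nearest region. The exact tests of the lists treat such genes as independent, which matters most where an adjusted p is close to the threshold.

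Liver genes stood at the other end. Only G6pc and Hp, each with 1 region, of 18 liver genes (11.1%, 1.38 to 34.7%) had one within 50 kb, and none had one within 10 kb, where a count of 0 allows up to 16.7% by the limit of 3 counts (exact upper limit 18.5%). Of 17 housekeeping genes, 13 (76.5%, 50.1 to 93.2%) had a region within 50 kb, among them Actb with 4, Pgk1 and Ywhaz with 2 each and B2m and Eef1a1 with 1 each. Within 10 kb the housekeeping share was 23.5%, against 23.8% of other genes.

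The share of genes with a region did not pass the test for the remaining lists. It was 73.3% of 15 trophectoderm genes, where Tfap2c had 5 regions, Id2 had 3 and Cdx2, Fgfr2, Gata3 and Tead4 had 2 each. It was 62.5% of 24 neuroectoderm genes, where Neurog1 and Zfp521 had 4 regions each, Six3 had 3 and Dll1, Hes5 and Meis1 had 2 each. Mesendoderm genes (55.0% of 20) included T, the mesoderm factor Brachyury, with 4 regions, Hnf4a and Wnt3 with 3 each, Gsc with 2 and Evx1 and Foxa2 with 1 each. Chromatin regulators (60% of 20) included Smarcc1 with 5, Eed with 4, Arid1a and Rad21 with 3 each and Chd7 and Hmgb1 with 2 each. Mitosis and cell cycle genes (58.3% of 24) included Ccnd3 with 4, Aurka, Bub1b, Ccna2 and Top2a with 2 each and Bub1 with 1. Fibroblast genes (46.7% of 15) included Fn1 with 4, Col3a1 with 2 and Col1a1, Col1a2, Loxl1 and Thy1 with 1 each.

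By Fisher's exact test with adjustment over 11 lists, the odds ratio was 9.61 for pluripotency (adjusted p = 8.12e-07), 4.56 for signalling (0.00801), 3.598 for formative and primed genes (0.0493), 3.90 for housekeeping (0.0364) and 0.150 for liver (0.0123). Adjusted p was 0.0687 for trophectoderm, 0.163 for neuroectoderm, 0.308 for mitosis, 0.319 for chromatin regulators, 0.552 for mesendoderm and 1 for fibroblast genes. Within 10 kb the housekeeping call ended in the same exact test (odds ratio 0.988, adjusted p = 1), while neuroectoderm (odds ratio 2.72, adjusted p = 0.0294) and trophectoderm (odds ratio 3.67, adjusted p = 0.0278) passed the test. When only the nearest gene of each region was counted, the liver call ended in the exact test (odds ratio 0.354, adjusted p = 0.255).

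**Figure D3:**
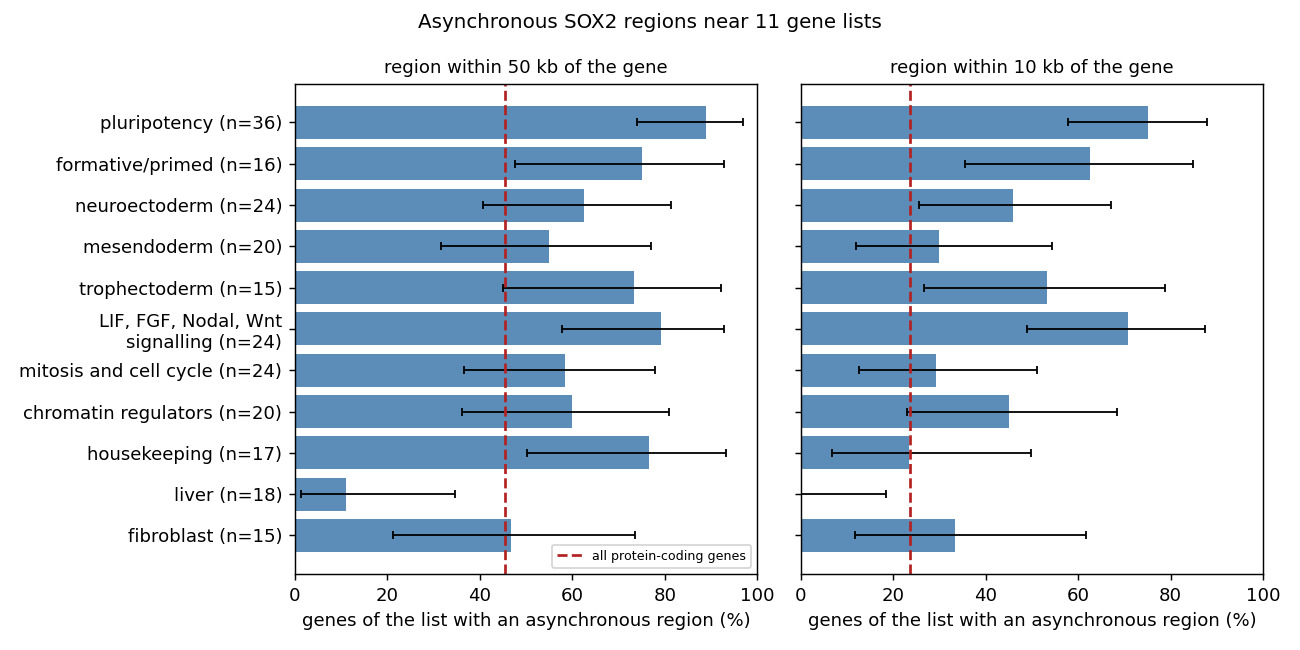
Share of the genes of each of 11 fixed lists with an asynchronous SOX2 region within 50 kb (left) or 10 kb (right) of the gene span, in percent; bars are shares with exact 95% intervals, n is the number of genes and the dashed line is the share of all protein-coding genes. Pluripotency genes reach 88.9% and 75%, liver genes 11.1% and 0%, and housekeeping genes fall from 76.5% to 23.5%, the level of all genes.

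Of the listed genes, only B2m and Gata2 had a mitotic region within 50 kb. Within 50 kb of a mitotic region were 183 protein-coding genes, of which 129 also had an asynchronous region within 50 kb. The listed genes among them were 2 of 228 (0.877%), close to the 0.836% of all protein-coding genes: B2m, a component of MHC class I (chromosome 2, 122147687 to 122153082), and Gata2, a trophectoderm and blood transcription factor (chromosome 6, 88193891 to 88207032). Both also had 1 asynchronous region within 50 kb. Neither had a mitotic region within 10 kb. The region counted for B2m was the one inside Spg11, and that for Gata2 lay 2.04 kb from Eefsec, its nearest gene.

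No pluripotency gene of 36 was near a mitotic region, which allows a share of up to 8.33% by the limit of 3 counts (exact upper limit 9.74%), and matched random lists had 0.242 such genes on average. Against genes near asynchronous regions only, the odds ratio was 5.39 for trophectoderm (Fisher's exact p = 0.184) and 4.49 for housekeeping (exact p = 0.213), and all 11 adjusted p were 1. With so few genes predicted, an absence near the pluripotency list was not detectable.

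The regions were spread over the chromosomes in both conditions. Asynchronous regions had a density of 4.19 per Mb on autosomes, from 2.67 on chromosome 14 to 5.39 on chromosome 11. The X chromosome, which carries Pgk1, had 173 regions, or 1.01 per Mb. These densities are not corrected for the number of copies of a chromosome per cell. Mitotic regions were most numerous on chromosome 5, with 9, among them those at Pisd and Kit, and none lay on chromosome 19, X or Y. By length, mitotic density was highest on chromosomes 17 (8.44 per 100 Mb) and 15 (7.71 per 100 Mb), above chromosome 5 (5.93 per 100 Mb). The chromosome counts of the conditions did not differ by a permutation test (chi-square 24.8, p = 0.180). On X, the asynchronous share predicted 1.40 mitotic regions, so that a count of 0 was not distinguishable from it (Fisher's exact p = 0.407).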

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

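The alternatives chosen only after the results were seen were genes with either end within 50 kb, draws weighted by width, and leaving out the narrowest mitotic regions. Of 82 recomputed values over 21 results, 61 kept their direction and side of the threshold, or stayed within 1.5 times for counts. Region counts fell to 5170 asynchronous and 42 mitotic above the median width, by construction, and overlaps to 3 of those 42; under the other overlap settings 6 to 9 overlapped, each with a permutation p of 0.000999. Pluripotency, signalling and formative genes passed under every setting run, with odds ratios of 6.26 to 11.8, 4.56 to 8.51 and 3.598 to 19.9, the highest by nearest gene. Against matched lists, neuroectoderm (observed over expected 1.70) and trophectoderm (1.92) came to pass. Within 10 kb the odds ratios were 2.72 for neuroectoderm and 3.67 for trophectoderm, both past the threshold, and 0.988 for housekeeping, which turned. By nearest gene, neuroectoderm (8.51), mesendoderm (2.83) and trophectoderm (5.67) passed, mitosis (0.745) and housekeeping (0.606) turned without passing, and liver (0.354) no longer passed. With regions above the median width, neuroectoderm (3.25) and trophectoderm (4.12) passed, mesendoderm (0.686) and mitosis (0.914) turned without passing, and housekeeping (1.92) no longer passed. Listed genes near a mitotic region numbered 0 within 10 kb and 0 by nearest gene. The cause was not tested in these cases. Not run were the motif settings, which need genome sequence, a shared q threshold, which needs q values, and width as an alternative rank, since width was already used. No paired analysis was possible because each list pools its replicates, and for that reason no replicate could be left out. The unknown depth limits every comparison of counts between the lists.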

Other observations

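The tests of gene families, clusters, gene coverage, peak numbers and distances between regions were chosen only after results were seen. So were the tests of thresholds, depth, sort purity, random background and pseudogenes near the non-overlapping regions; those of gene proximity and of pseudogenes near shared regions were chosen before.

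Some families of genes that share a symbol stem had few asynchronous SOX2 regions. Among 102 families of gene symbols with the same stem, 154 of 1110 olfactory receptor genes (Olfr, 13.9%) had a region within 50 kb, against 47.2% of other genes, and 38 of 355 vomeronasal receptor genes (Vmn, 10.7%). None of 33 reproductive homeobox genes (Rhox) or 26 kallikrein genes (Klk) had one, and 1 of 25 prolactin family genes (Prl) did. These 5 families passed both Fisher's exact test (adjusted p = 1.17e-115 for Olfr and 0.000100 for Prl) and the comparison with matched lists (adjusted p = 0.0051 for Olfr, where 243 genes were predicted, and 0.0204 for Prl). Solute carriers (Slc) had more, 215 of 375 (57.3%, Fisher's exact test, adjusted p = 6.54e-05), but did not pass against matched lists (adjusted p = 0.0816). Keratin genes (Krt, 23 of 53, 22.1 predicted) and keratin-associated protein genes (Krtap, 14 of 56, 13.9 predicted) were near the number from matched lists. Cytochrome P450 genes (Cyp, 30 of 99, 44.9 ± 4.84 predicted) and secretoglobin genes (Scgb, 3 of 40, 9.65 ± 2.65 predicted) were below it but missed the adjusted threshold against matched lists (permutation test, adjusted p = 0.0578 and 0.113). The Rhox genes lie on X, where asynchronous density was 24.2% of that on autosomes, and the matched lists did not hold the chromosome fixed. Neighbouring members of a family are not independent, and mappability was not measured.

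Asynchronous regions were clustered along the genome. Joined within 10 kb (a slightly wider distance was tried first) they made 9334 clusters, against 9912 ± 18.6 (SD) in 100 random placements. In clusters of at least 2 were 18.2% of regions, for which no share from random placement is given. Clustering was not separated here from a preference for places near genes. The cluster with the most regions had 6, at chromosome 7, 3193100 to 3217784. Its midpoint lay 13.2 kb from Nlrp12, a gene of innate immunity and the nearest protein-coding gene. The cluster spans 24.7 kb, so its edge lay closer to Nlrp12 than its midpoint. Non-coding genes were not considered, and which gene a cluster acts on was not tested. A cluster of 5 had its midpoint 13.8 kb from Nrf1, a regulator of mitochondrial genes (chromosome 6, 30159583 to 30174862). Another cluster of 5 lay inside Myo10, a myosin of filopodia (chromosome 15, 25753915 to 25774178). Clusters of 4 included those at Hes3, at Phc1, a Polycomb subunit, and at Sox5, which encodes another SOX factor. Sox2 was the gene of at least 1 kb most covered by a single region, at 83.5%, followed by Rrs1 at 25.4%.

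Of the numbers in the peak names, 66.4% are listed in the asynchronous and 64.1% in the mitotic list, and what removed the others, beside the blacklist, is not given in the sources used here. Of the numbers spanned on X, 88.7% (exact 95% interval 83.4 to 92.8%) are listed, against 66.3% on autosomes (61.8 to 70.1% per autosome, Fisher's exact p = 1.10e-12). Asynchronous density on X, not corrected for the number of copies per cell, was 24.2% of that on autosomes. In 145 of 315 regions with lettered summits a letter is missing, although the summits of a region share its coordinates, so these entries were not lost by coordinates alone.

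Mitotic cells had 0.812% as many regions as asynchronous cells. A difference in q threshold would work the other way, since the looser one belongs to the mitotic list. A lower depth or antibody yield of the mitotic libraries remains open, because 0 of the 2 lists carry depth or read counts. Loss of SOX2 from mitotic chromatin, the biological alternative in the design, remains open for the same reason and was not tested. The mitotic cells also underwent overnight nocodazole arrest, staining and sorting, whose effects cannot be separated here from those of mitosis.

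The 9 shared regions exceeded chance also for placements matched on distance to genes (permutation p = 0.000999). The matching used coarse classes: inside a gene, up to 10 kb outside, up to 50 kb outside and further. At that resolution the result argues against a common preference for places near genes. Gene ends were not matched, and the shared regions at Nrarp and Abcg1 lay within 1 kb of one. A common preference for gene ends was therefore not tested. Asynchronous cells left in the sort for H3S10p could bring in the strongest asynchronous regions, but width is the only rank here. The median width percentile of the shared regions, 86.9 (exact interval 19.3 to 96.0), leaves this open. Multi-copy sequence remains open too. Its stand-in here, a pseudogene within 10 kb, was found for 11.1% of shared regions (1 of 9) and 7.57% of the others (Fisher's exact p = 0.508). Retained binding in mitosis is a hypothesis that these values do not separate from the open ones.

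The 75 mitotic regions without an overlap lay a median of 36.6 kb from an asynchronous region, below the matched placements (59.6 to 123 kb), which argues against calls scattered at random given gene distance. Background at open or well-mapped chromatin was not tested. A candidate explanation for part of them is multi-copy sequence: 13 (17.3%, exact 95% interval 9.57 to 27.8%) had a pseudogene within 10 kb, against 7.57% of asynchronous regions (odds ratio 2.56, Fisher's exact p = 0.00666) and 7.16% of matched placements (permutation p = 0.003). A nearby pseudogene is only a stand-in for multi-copy sequence, since neither sequence nor mappability was used here. Matched placements gave a mean of 5.37 such regions, so part of the 13 would be found without this explanation. These 13 include the regions inside Rmc1 and Zfp661 and those 9.44 kb from Nyap1 and 63.7 kb from Prl2c3. For the other regions, binding near asynchronous sites during mitosis and background at open chromatin both remain open. Neither is excluded for the 13. The other regions include those near Sall1, Myc and Kit, which were at or close to the smallest mitotic width. These lay nearer to an asynchronous region than most of the 75 did, but were singled out after the distances were seen. The nearest of the 75, at 1.74 kb, was the region 63.7 kb from Prl2c3, which is among the 13.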
